A study of Mus musculus with 9 samples.

How the data were processed

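RNA was measured in 9 samples of mouse embryos at embryonic day 16.5: 3 of the condyle of the temporomandibular joint, 3 of the fossa of the same joint and 3 of the whole body. Per the labels' protocols, all 9 samples share a single treatment entry, laser capture of frozen tissue, and a single RNA isolation kit. The series' design text calls the samples biological triplicates but does not say which embryo each came from, so the p-values measure the spread between these samples. Whether a condyle and a fossa sample came from the same embryo is not given in the sources used here. Biotin-labelled cRNA was hybridised to an Affymetrix mouse array with 45101 probe sets, per the labels' protocols and the platform annotation.

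The deposited values are intensities on a linear scale, 1 column per array, as the values themselves show: the lowest is 3.25 and the highest 67158.9. The submitters' processing notes name limma, with no version and no role. How the authors corrected the background, normalized the arrays and summarised the probes is not given in the sources used here. Array medians were close to each other, with mean log2 medians of 2.80 in condyle, 2.77 in fossa and 2.91 in whole body, but the upper parts of the distributions were not aligned. The 75th percentile was 4.85 in condyle, 4.18 in fossa and 4.45 in whole body on the log2 scale. The deposited normalization was kept for the main results.

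Intensities were converted to log2 with a floor of 1, which no value was under. Probe sets were named through the platform annotation, whose symbols were updated through a RefSeq table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Of the probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none in the table used here, and 64 were array controls. Each gene was represented by the probe set with the highest mean over all 9 arrays, which gave 18193 genes. Among these, 9010 genes had several probe sets. Some genes of the fixed lists are not analysed here. The background limit of an array was the highest signal among 27 control probe sets for Bacillus subtilis transcripts. A gene was at background in a group when it was at or under that limit on all 3 arrays. For such a gene the fold is given as "at least", from the mean log2 value of the brighter group against the mean over the dimmer group's arrays of the higher of the limit and the gene's own value. The fold is given as "at least" in the same way, in place of a log2 difference, where the dimmer group had 1 array above the limit. Where it had 2, folds are given as "at least" and the log2 difference is that of the measured values. No fold is given where both groups were at background. The number of arrays limits the precision.

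Genes were tested with limma version 3.58.1 in R version 4.3.3, with lmFit and eBayes on all 9 arrays in 1 fit of 3 groups. The fit left 6 residual degrees of freedom, and the prior held 1.12 degrees of freedom. A moderated F test asked for any difference among the 3 groups. The 3 contrasts were condyle minus whole body, fossa minus whole body and condyle minus fossa. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Differences are given on the log2 scale with their standard errors (SE) from the fit, and levels as mean ± SD of 3 arrays.

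The gene lists, the rule for named genes and most of the other settings below were fixed before the data were examined. The 29 lists covered cartilage, bone, joint and fibrous tissue, signalling pathways, patterning factors, cell cycle, metabolism and stress. They also covered markers of other cell types and sex chromosome genes. Each list was set against all other genes with limma's camera test, with the preset inter-gene correlation of 0.01 and adjustment over the 29 lists and 3 contrasts together. Camera with a correlation estimated for each list, and the fry rotation test, were alternatives. Camera ranks a list relative to all other genes, so a list can be called down with a median near 0 when most genes lie above 0. Beside each list stands the number of members past the threshold over all genes and the number adjusted over the list alone.

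The genes named in the text follow a fixed rule. It took the 8 largest rises and the 8 largest falls per comparison among genes past the threshold whose 3 arrays of the first group lay beyond all 3 of the second. It then took up to 4 members with the largest absolute difference from each list described. It always added the Hedgehog genes Ihh, Shh, Ptch1, Gli1, Gli2, Hhip and Smo, the cartilage genes Sox9, Col2a1, Acan and Col10a1, and the bone genes Sp7, Col1a1 and Ibsp. Predicted genes and unnamed clones were passed over among the 8, which happened for 2 genes lower in condyle than in fossa.

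RNA quality was described by the 3 prime minus 5 prime log2 value of the Gapdh and Actb control probe sets. In a test chosen after the values were seen, the mean of both was set against whole body for each joint tissue, with a Welch 95% interval and a bound of 1 (log2). The groups were compared with exact two-sided permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1. The chance overlap of the 2 comparisons that share the whole body arrays was taken from 50 simulations of unchanged groups.

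The procedure was tested on simulated data for 18193 genes with 200 changed genes. In the simulated condyle and whole body comparison, 52% of changes of 1 on the log2 scale, 84% of changes of 2, 94% of changes of 3 and 96% of changes of 4 were recovered. The matching shares were 54%, 82%, 88% and 98% for fossa and whole body, and 60%, 78%, 84% and 96% for condyle and fossa. False calls made up 6.86%, 4.73% and 4.79% of calls, and simulations without any change gave 0 calls in each comparison. Of 21 simulated lists the 1 that was moved was called and 0 others were. The simulated genes were drawn independently of each other, so this does not test camera on lists whose members vary together. In the real data the estimated correlation was 0.424 for the cartilage list and 0.697 for the neuronal list.

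The other settings fixed at that time were quantile normalization, centring each array on its median, and leaving out the dimmest 40% of genes. The median of every array lay under its background limit, so centring on it aligns dim probe sets rather than measured signal. After quantile normalization the probe set of each gene was chosen anew by its mean, so a gene's value there may come from another probe set. Others were the mean of all probe sets of a gene, every probe set tested alone, an eBayes prior with trend and robust options, and the replicate number as a block. Further ones were 16 added before log2, array weights, only the 6 arrays compared, a minimum fold of 2, and each array left out in turn. Settings chosen after seeing the data left out genes at background on all 9 arrays, with and without quantile normalization, or raised all values to the highest background limit of the 9 arrays.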

Results

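Gene expression in the developing temporomandibular joint, the hinge between lower jaw and skull, was profiled on 9 arrays from mouse embryos at embryonic day 16.5. The groups were the condyle, the head of the lower jaw that moves in the joint, the fossa, the socket on the skull side, and the whole body as a reference, with 3 arrays each. On average 46.3% ± 0.80 (SD) of probe sets lay above background on the condyle arrays, 38.3% ± 7.07 on the fossa arrays and 42.0% ± 4.27 on the whole body arrays. Fossa array 1 had the lowest share, 30.3%. Across probe sets, which are not independent replicates, arrays correlated at 0.967 to 0.979 within condyle, 0.944 to 0.972 within fossa and 0.969 to 0.978 within whole body. Condyle and fossa arrays correlated at 0.939 to 0.971 with each other, and at 0.919 to 0.944 with the whole body arrays. The first principal component (40% of the variance) parted the joint tissues from the whole body and the second (23.1%) parted condyle from fossa. Among the 18193 genes, 5119 differed among the 3 groups in the moderated F test. This count was 3152 after quantile normalization, 3024 with a common floor, and 2809 after quantile normalization without genes at background.

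The comparison of condyle with whole body asks which transcripts mark the condyle. Cartilage matrix genes stood highest above the whole body. Acan, which encodes the proteoglycan aggrecan, was at least 86.2-fold higher, and Comp, which encodes an oligomeric cartilage matrix protein, was 44.3-fold higher, at 10.43 ± 0.48 (SD, n = 3, log2) against 4.96 ± 0.15. Col2a1, the main fibrillar collagen of cartilage, was at least 37.9-fold higher and Col9a3, a collagen chain found on its fibrils, 20.4-fold. Acan and Col2a1 were above background on 2 of the 3 whole body arrays. Genes of liver and blood stood lowest, led by the fetal plasma protein gene Afp, which was 2130-fold lower. In total 2398 genes differed, of which 1699 were higher and 699 lower in condyle.

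Of 25 measured cartilage genes, 16 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median log2 difference of 2.57 (camera adjusted p = 1.39e-10). With an estimated correlation the list had an adjusted p = 0.36. The log2 differences were 6.62 ± 0.67 (SE) for Acan (adjusted p = 0.00187), 5.47 ± 0.38 for Comp (adjusted p = 0.000374), 5.34 ± 0.81 for Col2a1 (adjusted p = 0.00783) and 4.35 ± 0.54 for Col9a3 (adjusted p = 0.00377). Sox9, a transcription factor of chondrocytes, was higher by 1.97 ± 0.33, but by 0.52 with adjusted p = 0.126 after quantile normalization, where probe sets were chosen anew. Other genes among the 8 largest rises were Wwp2, a ubiquitin ligase gene, at least 27.7-fold higher, the nuclear noncoding RNA Neat1 at 4.66 ± 0.78, Slc35e3 at 4.42 ± 0.40 and Mindy1 at 4.23 ± 0.41.

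Of 12 hypertrophic chondrocyte genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.0937), but was called up after quantile normalization (adjusted p = 0.0471). As deposited it had an adjusted p = 0.673 with an estimated correlation. Panx3, a channel gene of maturing chondrocytes and osteoblasts, was higher by 3.92 ± 0.73 and Pth1r, the parathyroid hormone receptor gene, by 2.71 ± 0.49. Vegfa was at least 1.72-fold higher. Mmp13 differed by 1.53 ± 1.35, which did not pass (adjusted p = 0.458), and Col10a1 and Ihh were at background in both groups. Of 25 bone genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0102; adjusted p = 0.673 with an estimated correlation; adjusted p = 0.157 after centring on the median). Col1a1, the main collagen of bone, was higher by 2.31 ± 0.58 (adjusted p = 0.0426; 0.0587 after quantile normalization) and Wif1, a secreted Wnt inhibitor, by 3.32 ± 0.68. Dmp1, a matrix protein gene of osteocytes, differed by 3.07 ± 1.13 (adjusted p = 0.128), Phex by 2.19 ± 1.52 (adjusted p = 0.364), Sp7 by 1.70 ± 0.56 (adjusted p = 0.0931) and Ibsp by 1.21 ± 0.95 (adjusted p = 0.414).

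Of 32 matrix remodelling genes 9 were higher and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 0.00112; adjusted p = 0.577 with an estimated correlation). They included the collagen chaperone gene Serpinh1 (3.95 ± 0.39), the gelatinase gene Mmp2 (3.52 ± 0.38) and the collagen hydroxylase genes Plod2 (3.30 ± 0.47) and P4ha2 (2.56 ± 0.46). Of 30 fibrous tissue genes 8 were higher and 3 lower (10 and 3 adjusted over the list alone, camera adjusted p = 0.0497; adjusted p = 0.722 with an estimated correlation). This call was lost after quantile normalization (adjusted p = 0.0816), without genes at background too (0.13), and after centring on the median (0.424).

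Of 23 Hedgehog pathway genes 6 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.00915; adjusted p = 0.36 with an estimated correlation). Gli2, a transcription factor of the pathway, was higher by 2.21 ± 0.24 (adjusted p = 0.0025), the receptor gene Ptch1 by 1.67 ± 0.38 (adjusted p = 0.0315) and Smo by 1.10 ± 0.28 (adjusted p = 0.043). Ptch1 had 3 probe sets, of which 1 had this direction. Smo had an adjusted p = 0.097 after quantile normalization. Gli1 was above background on all 3 condyle arrays and on 0 of the whole body arrays, but its fold of at least 4.06 did not pass (adjusted p = 0.0658). Boc differed by 1.51 ± 0.42 (adjusted p = 0.057), and Shh (at least 1.11-fold, adjusted p = 0.296) and Hhip (at least 1.23-fold, adjusted p = 0.319) did not pass either.

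Of 38 craniofacial patterning factors 7 were higher and 1 lower (12 and 3 adjusted over the list alone, camera adjusted p = 0.0498; adjusted p = 0.521 with an estimated correlation). The call was lost after quantile normalization (adjusted p = 0.0907), after centring on the median (0.199) and after quantile normalization without genes at background (0.13). Pax9 was higher by 3.19 ± 0.30, Dlx1 by 2.20 ± 0.34, Dlx5 at least 2.12-fold, and the mesoderm factor gene Meox2 fell by 2.48 ± 0.46. Of 33 Hox genes, which pattern the trunk, 0 were higher and 3 lower, and 12 were at background in both groups (0 and 2 adjusted over the list alone; median -0.17; camera adjusted p = 0.000196; adjusted p = 0.36 with an estimated correlation). Hoxa9 was at least 22.9-fold lower and Hoxc8 at least 6.41-fold lower. Hoxa5 fell by 1.87 ± 0.48 (adjusted p = 0.0512 after quantile normalization) and Hoxb3 differed by -1.89 ± 0.57 (adjusted p = 0.0723).

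Of 34 cell cycle genes 12 were higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.00345; adjusted p = 0.577 with an estimated correlation; adjusted p = 0.084 after quantile normalization). Ccnd1, the gene of cyclin D1, was higher by 1.60 ± 0.20, the mitotic kinesin gene Kif20a by 2.21 ± 0.43 and the mitotic kinase gene Aurkb by 1.45 ± 0.19, while Ccne2 fell by 2.59 ± 0.47. Kif20a and Aurkb had adjusted p = 0.0507 and 0.0503 after quantile normalization. Of 25 hypoxia and glycolysis genes 10 were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.000135; adjusted p = 0.175 with an estimated correlation). The glycolytic enzyme genes Pkm and Aldoa were higher by 3.18 ± 0.35 and 2.20 ± 0.16, P4ha1 by 2.46 ± 0.56 (adjusted p = 0.0587 after quantile normalization) and the stress response gene Ddit4 by 2.25 ± 0.21.

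Markers of other organs were lower in condyle. Of 24 liver genes 20 were lower and 0 higher (21 and 0 adjusted over the list alone; median -5.95; camera adjusted p = 2.95e-28; adjusted p = 0.0642 with an estimated correlation). Afp fell by 11.05 ± 0.42 (adjusted p = 2.25e-05) and Alb, the albumin gene, by 9.27 ± 0.30 (adjusted p = 1.05e-05), while Apoa1 was at least 245-fold and Serpina1b at least 124-fold lower. Outside these lists Apom, an apolipoprotein gene, was at least 401-fold and the lens crystallin gene Crygf at least 172-fold lower. Of 18 erythroid genes 11 were lower and 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 2.26e-11; adjusted p = 0.0217 with an estimated correlation). Hemgn fell by 7.84 ± 0.67, Ermap by 5.72 ± 0.23, the embryonic globin gene Hbb-bh1 by 5.07 ± 0.70 and Slc4a1 by 4.86 ± 0.93. Of 16 heart muscle genes 7 were lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 7.62e-08; adjusted p = 0.0792 with an estimated correlation). The myosin light chain genes Myl2 and Myl3 fell by 5.98 ± 0.23 and 5.20 ± 0.54, and Myh6 was at least 33.3-fold lower. Of 37 skeletal muscle genes 7 were lower and 0 higher (14 and 0 adjusted over the list alone, camera adjusted p = 1.47e-05; adjusted p = 0.577 with an estimated correlation). Myh7 fell by 4.36 ± 0.49, Myl4 by 3.19 ± 0.75 and Mylpf by 3.09 ± 0.72, and Myl1 differed by -3.85 ± 1.10 (adjusted p = 0.0638). Myh7 also belongs to the heart muscle list, so its fall does not speak for skeletal muscle alone.

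Of 25 macrophage and leukocyte genes 7 were lower (8 adjusted over the list alone, camera adjusted p = 1.41e-05; adjusted p = 0.44 with an estimated correlation). Of 25 gut, lung, kidney and pancreas genes 3 were lower (5 adjusted over the list alone, camera adjusted p = 6.78e-05; adjusted p = 0.175 with an estimated correlation). They included the fatty acid binding protein gene Fabp1, at least 544-fold lower. Of 39 Wnt pathway genes 7 were higher (9 adjusted over the list alone, camera adjusted p = 0.0498; adjusted p = 0.577 with an estimated correlation; adjusted p = 0.16 after centring on the median). No other list was called. Of 32 BMP and TGF-beta genes 5 were higher, of 21 FGF genes 4, of 23 stress genes 3, of 20 joint genes 2, of 21 Notch genes 2 and of 16 osteoclast genes 2, with 2 osteoclast genes lower. The same numbers passed when adjusted over the list alone, except for 5 stress genes. Of 22 endothelial genes 1 was lower in both counts, and of 4 sex chromosome genes 1 was lower (1 higher and 1 lower adjusted over the list alone). No gene passed among 28 neuronal, 11 glial, 25 epithelial and 14 fat genes. The mean of the 25 epithelial genes was 7.04 to 8.38 (log2) on the condyle arrays, above 6.21 to 6.48 in whole body. The fit takes its spread from all 3 groups, and this mean ran from 4.49 to 8.03 on the fossa arrays. So the lack of calls does not show equal epithelial signal. The 18S ribosomal RNA control, a sign of how much ribosomal RNA was labelled, was lower by 5.99 on the log2 scale in condyle (8.33 ± 2.10 against 14.32 ± 0.09, SD, n = 3; exact permutation p = 0.1, the smallest possible).

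In this comparison 53.2% of genes had 3 arrays beyond the other 3, where chance gives 10%. After quantile normalization 1631 genes differed, 822 higher and 809 lower, so that the share of higher genes moved from 70.9% to 50.4%, and the count was between 1470 and 1585 without any single condyle array or without whole body array 2.

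**Figure D1:**
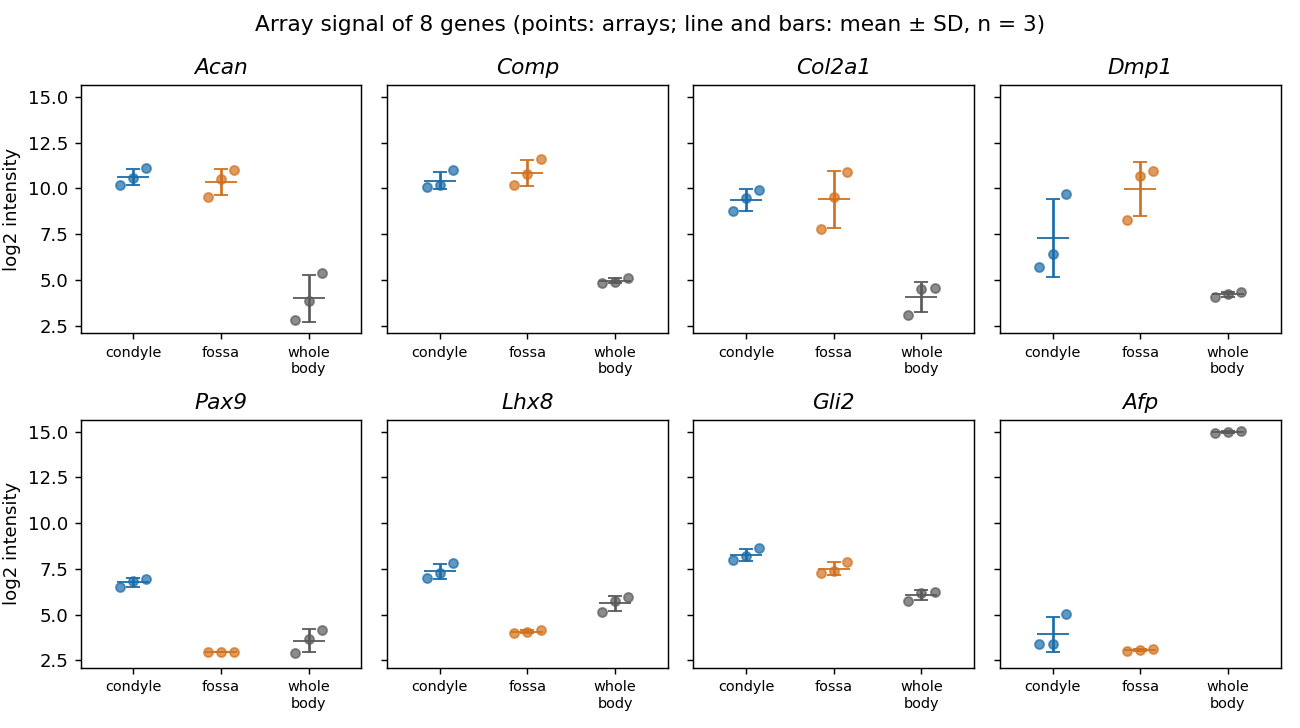
Log2 intensity of 8 genes on the 9 arrays, with points for arrays and lines for the mean ± SD of 3 arrays of condyle, fossa and whole body. Acan, Comp and Col2a1 were high in both joint tissues, Pax9 and Lhx8 were higher in condyle than in fossa, and Afp was near 14.98 in whole body alone.

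The comparison of fossa with whole body asks the same question of the socket. The same cartilage genes led: Acan was at least 71.4-fold higher, Comp 59.9-fold, Col2a1 at least 38.4-fold and Col9a3 22.1-fold. Dmp1 was among the largest rises here, 54.0-fold higher at 9.96 ± 1.49 (SD, n = 3, log2) against 4.21 ± 0.12. Liver genes again stood lowest, with Afp at least 3530-fold lower and above background on 1 fossa array. In total 3559 genes differed, 726 higher and 2833 lower in fossa.

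Of 25 cartilage genes 15 were higher and 0 lower (17 and 1 adjusted over the list alone), with a median of 2.63 (camera adjusted p = 3.09e-13; adjusted p = 0.304 with an estimated correlation). The log2 differences were 6.35 ± 0.67 (SE) for Acan (adjusted p = 0.00132), 5.90 ± 0.38 for Comp (adjusted p = 0.000167), 5.36 ± 0.81 for Col2a1 (adjusted p = 0.00501), 4.46 ± 0.54 for Col9a3 and 4.03 ± 0.53 for Col9a1. Neat1 was higher by 5.25 ± 0.78 and Wwp2 at least 19.1-fold. Sox9 differed by -0.36 ± 0.33 (adjusted p = 0.491), and by 0.12 after quantile normalization. Of 25 bone genes 5 were higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 3.58e-05; adjusted p = 0.563 with an estimated correlation). Dmp1 was higher by 5.76 ± 1.13 (adjusted p = 0.0132), Col1a1 by 2.86 ± 0.58 (adjusted p = 0.0152) and Col1a2 by 2.55 ± 0.48, while Phex differed by 4.20 ± 1.52 (adjusted p = 0.0988), Ibsp by 2.52 ± 0.95 (adjusted p = 0.111) and Sp7 by 1.04 ± 0.56 (adjusted p = 0.242). Of 12 hypertrophic chondrocyte genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0033; adjusted p = 0.537 with an estimated correlation). Pth1r was higher by 3.10 ± 0.49 and Panx3 by 2.67 ± 0.73, and Mmp13 differed by 3.16 ± 1.35 (adjusted p = 0.152). Col10a1 and Ihh were at background in both groups, as was Shh.

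Of 32 matrix remodelling genes 5 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.000196; adjusted p = 0.577 with an estimated correlation). Serpinh1 was higher by 3.79 ± 0.39, Mmp2 by 2.28 ± 0.38 and Adamts20 by 2.12 ± 0.58. Of 30 fibrous tissue genes 5 were higher and 3 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.00991; adjusted p = 0.714 with an estimated correlation; adjusted p = 0.234 after centring on the median). Of 23 Hedgehog genes 1 was higher and 1 lower (1 and 0 adjusted over the list alone), and the list was called up (camera adjusted p = 0.0498; adjusted p = 0.537 with an estimated correlation; adjusted p = 0.11 after quantile normalization). The higher gene was Gli2, by 1.44 ± 0.24 (adjusted p = 0.00746). Ptch1 differed by 1.12 ± 0.38 (adjusted p = 0.0851), but was higher by 1.66 with adjusted p = 0.0278 after quantile normalization. Boc differed by 1.37 ± 0.42 and Smo by 0.41 ± 0.28, and the folds of Gli1 and Hhip were at least 1.96 and 1.10, none past the threshold. Boc too was higher after quantile normalization, by 1.66 with adjusted p = 0.046.

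Of 34 cell cycle genes 11 were lower and 1 higher in fossa than in whole body (17 and 1 adjusted over the list alone; median -0.68; camera adjusted p = 0.00343; adjusted p = 0.577 with an estimated correlation). After quantile normalization the list had a median of -0.28 and an adjusted p = 0.121. Ccne2 fell by 3.31 ± 0.47, Pcna, the sliding clamp gene of DNA replication, by 2.35 ± 0.30 and Nusap1 by 1.62 ± 0.28, and Ccnd2 differed by -1.44 ± 0.88 (adjusted p = 0.304).

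Of 24 liver genes 21 were lower and 0 higher (22 and 0 adjusted over the list alone; median -6.23; camera adjusted p = 5.2e-22; adjusted p = 0.0792 with an estimated correlation). Afp was at least 3530-fold lower (adjusted p = 1.44e-05), Alb at least 1150-fold, Apoa1 at least 208-fold and Apoa2 at least 140-fold. Fabp1 was at least 410-fold and Apom at least 318-fold lower, and the differences were -7.84 ± 0.96 for the neutrophil gene S100a8 and -7.33 ± 0.21 for Crygf. Of 18 erythroid genes 12 were lower and 0 higher (14 and 0 adjusted over the list alone, camera adjusted p = 3.48e-07; adjusted p = 0.0425 with an estimated correlation). Hemgn fell by 7.09 ± 0.67, Slc4a1 by 6.20 ± 0.93, Hbb-bh1 by 5.83 ± 0.70 and Ermap by 5.47 ± 0.23. Of 37 skeletal muscle genes 9 were lower and 0 higher (12 and 0 adjusted over the list alone, camera adjusted p = 0.00991; adjusted p = 0.714 with an estimated correlation). Myh7 fell by 4.15 ± 0.49, Tnnc1 by 3.33 ± 0.70 and Myl4 by 3.04 ± 0.75 (adjusted p = 0.0604 after quantile normalization), and Myl1 differed by -3.13 ± 1.10 (adjusted p = 0.0924). Myh7 also belongs to the heart muscle list, so its fall does not speak for skeletal muscle alone.

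Of 16 heart muscle genes 8 were lower (9 adjusted over the list alone, camera adjusted p = 0.000196; adjusted p = 0.197 with an estimated correlation), and of 25 macrophage and leukocyte genes 6 (7 adjusted over the list alone, camera adjusted p = 0.019; adjusted p = 0.644 with an estimated correlation). Of 22 endothelial genes 1 was higher and 2 lower, over all genes as over the list alone, and the list was called up (camera adjusted p = 0.0498; adjusted p = 0.714 with an estimated correlation; adjusted p = 0.182 after quantile normalization). The other lists were not called. Among 33 Hox genes 2 were higher and 7 lower (2 and 8 adjusted over the list alone; called down after quantile normalization without genes at background, adjusted p = 0.037, but adjusted p = 0.714 with an estimated correlation as deposited), and among 38 craniofacial factors 3 and 7, with the same numbers over the list alone. Among 25 hypoxia genes 4 were higher and 8 lower (6 and 9 adjusted over the list alone), among 39 Wnt genes 3 and 4 (3 and 2), among 21 FGF genes 3 and 4 (3 and 5) and among 23 stress genes 2 and 3 in both counts. Among 32 BMP and TGF-beta genes 3 were lower (1 adjusted over the list alone), among 25 gut, lung, kidney and pancreas genes 1 was higher and 4 lower (1 and 5; called down in the same setting, adjusted p = 0.00677, but adjusted p = 0.577 with an estimated correlation as deposited), and among 16 osteoclast genes and 14 fat genes 2 each were lower. Joint genes had 1 higher and 1 lower, Notch genes 1 higher, and epithelial and sex chromosome genes 1 lower each, all in both counts. No neuronal or glial gene passed. The 18S ribosomal RNA control was lower by 5.73 on the log2 scale in fossa than in whole body (8.59 ± 1.23 against 14.32 ± 0.09, SD, n = 3; exact permutation p = 0.1, the smallest possible).

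In this comparison 42.2% of genes had 3 arrays beyond the other 3, where chance gives 10%, and 394 of the called genes were at background in both groups. The share of higher genes, 20.4%, was 47.4% after quantile normalization (1471 higher, 1633 lower) and 44.7% after centring each array on its median (1646 higher, 2035 lower), and without fossa array 3 the count was 2343. The array medians lay under the background limits, so the share after centring cannot speak for measured signal.

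Condyle and fossa shared much of their difference from the whole body. Against whole body 440 genes were higher in both and 632 lower in both, 1072 in all. Independent lists of these sizes would share 67.8 higher and 108.8 lower genes. Unchanged groups set against the same 3 whole body arrays shared at most 1 gene in 50 simulations, but such groups give almost no calls, so this count does not measure what the shared arrays add. The log2 differences of the 2 comparisons correlated at 0.762 across genes, against 0.502 in the simulations, and their covariance was 0.564 against 0.0603. The 3 whole body arrays were too few to be split into parts of at least 2 arrays, so part of the excess in shared genes may come from the shared controls. The covariance is the fairer comparison, because shared arrays add the same covariance with or without real differences. It bears on the shared whole body arrays only, because the simulations held no offset common to the condyle and fossa arrays. The 18S control was lower than in whole body by 5.99 in condyle and 5.73 in fossa (log2). A technical offset common to both joint tissues was therefore not told apart from shared biology.

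**Figure D2:**
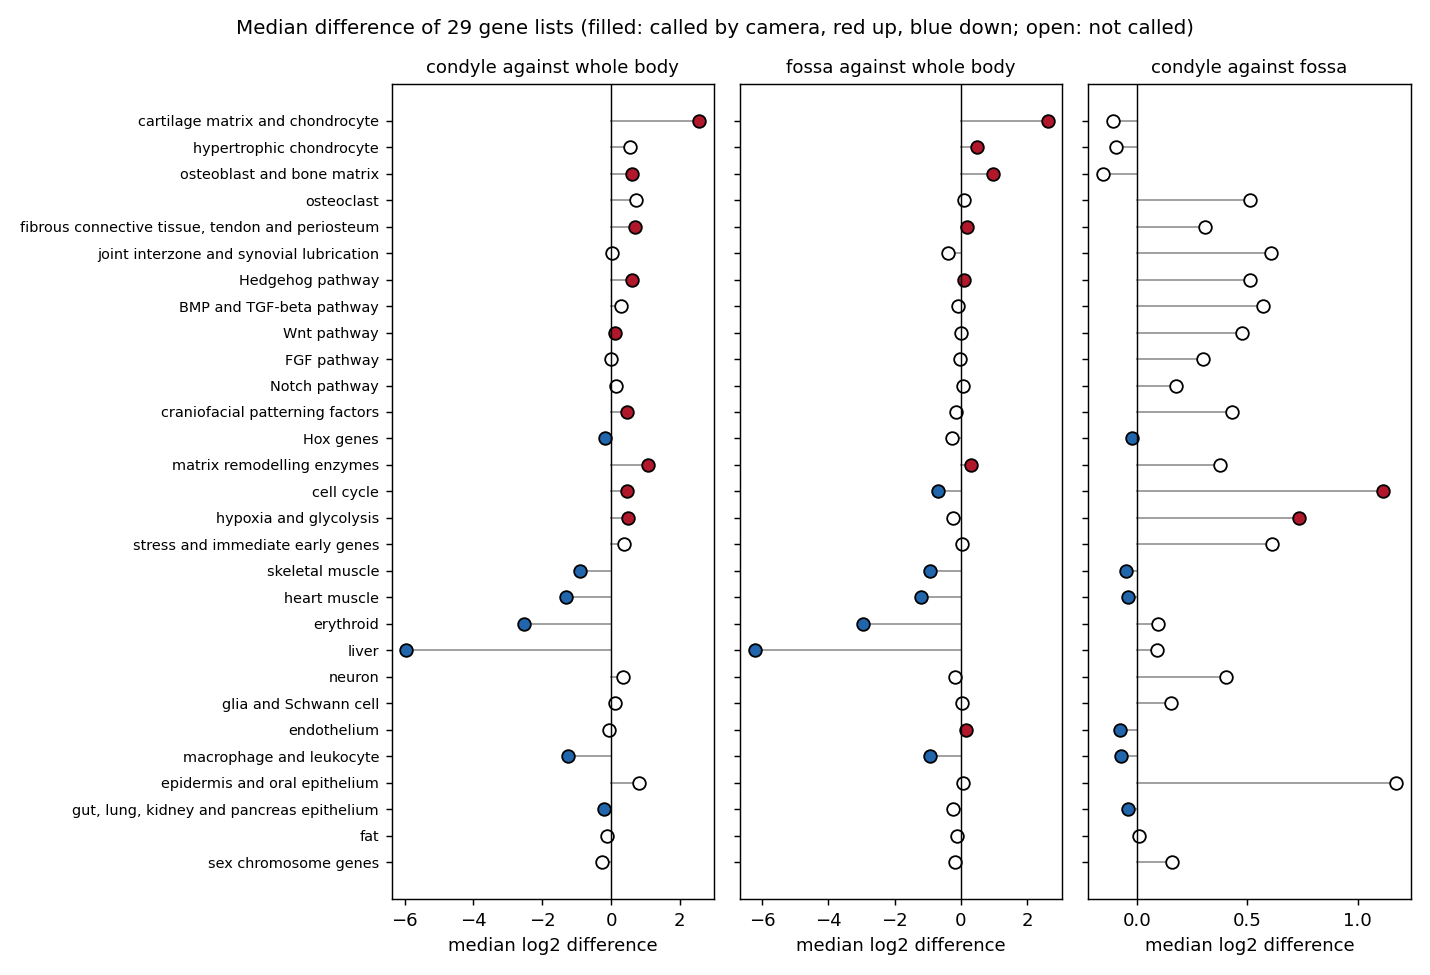
Median log2 difference of 29 gene lists in 3 comparisons, with filled points for lists called by camera (red up, blue down) and open points for the others; the axis of the condyle and fossa panel is narrower. Cartilage genes had medians of 2.57 and 2.63 against whole body and -0.11 between condyle and fossa, where cell cycle genes had 1.12.

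The comparison of condyle with fossa asks which transcripts part the 2 sides of the joint. Developmental transcription factors stood among the genes higher in condyle. Pax9 was at least 12.1-fold higher in condyle, at 6.77 ± 0.23 (SD, n = 3, log2) against 2.97 ± 0.01, and above background on 1 of the 3 fossa arrays. Lhx8, a factor of the first pharyngeal arch, was 9.78-fold higher. The chloride channel family gene Clic6, above background on 2 fossa arrays, was at least 21.2-fold and Tac1, the gene of the neuropeptide substance P, 12.8-fold higher. Eya4, a transcriptional coactivator gene, was 3.71-fold lower. Of 34 cell cycle genes 21 were higher in condyle, and of 25 cartilage genes 2. In total 3440 genes differed, 3053 higher and 387 lower in condyle. After quantile normalization 1178 genes differed, 684 higher and 494 lower, and 966 of the 3440 genes were still called, 963 of them with the same sign. The log2 difference changed sign for 191 of the 3440 genes. The share of higher genes was 88.8% and 58.1% in these settings, and the median difference of all genes was 0.21 and -0.01. Quantile normalization without genes at background gave 379 genes, 244 higher and 135 lower, and 341 of the 3440 genes were still called. A common floor gave 1823 genes, 1782 higher and 41 lower.

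Of 38 craniofacial patterning factors 11 were higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 0.43. The list was not called against other genes (camera adjusted p = 0.217). Pax9 was higher at least 12.1-fold (adjusted p = 0.000804), Lhx8 by 3.29 ± 0.26 (SE; adjusted p = 0.00083), and Six2 at least 4.41-fold (adjusted p = 0.00245). Gsc was at least 4.50-fold higher (adjusted p = 0.0252), but had an adjusted p = 0.131 after quantile normalization. The other largest rises were Clic6 at 4.70 ± 0.75, Tac1 at 3.67 ± 0.29, the heparan sulfate enzyme gene Hs3st3a1 at least 7.37-fold, Txlna at 3.13 ± 0.31, the lipid transfer gene Stard5 at least 7.89-fold and Erlin2 at least 6.39-fold. The largest falls were smaller. Eya4 fell by 1.89 ± 0.46 (adjusted p = 0.0291), the bone matrix gene Mepe by 1.33 ± 0.30 (adjusted p = 0.0246), and Nhlrc3 by 1.45 ± 0.11. Pik3r6 was at least 2.86-fold, the cadherin gene Cdh3 at least 2.73-fold, Tff1 at least 2.22-fold, and Myh6 and Fcgr1 at least 1.95-fold lower. Cdh3 had an adjusted p = 0.0636 after quantile normalization.

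Of 34 cell cycle genes 21 were higher and 0 lower (25 and 0 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 5.44e-08; adjusted p = 0.291 with an estimated correlation). After quantile normalization the median was 0.49 (camera adjusted p = 1.51e-05). Ccnd1 was higher by 1.91 ± 0.20 (adjusted p = 0.00183), the replication helicase genes Mcm3 and Mcm2 by 1.79 ± 0.12 (adjusted p = 0.000519) and 1.56 ± 0.22 (adjusted p = 0.00466), and the mitotic kinase gene Plk1 at least 2.38-fold. Mcm2 had an adjusted p = 0.0985 after quantile normalization. Of 25 hypoxia and glycolysis genes 14 were higher and 0 lower, over all genes as adjusted over the list alone (median 0.74; camera adjusted p = 0.000196; adjusted p = 0.175 with an estimated correlation). Ldha was higher by 1.98 ± 0.24, Pgam1 by 1.70 ± 0.12, Pfkl by 2.22 ± 0.40 and Pkm by 1.97 ± 0.35. After quantile normalization the median of this list was 0.18 (camera adjusted p = 0.0139), with adjusted p = 0.0597 for Pfkl and 0.1 for Pkm.

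Of 32 BMP and TGF-beta genes 7 were higher and 0 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.325). The receptor gene Tgfbr1 was higher by 1.62 ± 0.37, and Ltbp2, Fst and Id1 differed by 2.00 ± 0.63, 1.75 ± 0.55 and 1.57 ± 0.51 without passing. Of 39 Wnt genes 6 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.605). The receptor gene Fzd6 was higher by 2.19 ± 0.30 and the target gene Axin2 by 1.96 ± 0.55, while Fzd7 and Nkd1 differed by 1.75 ± 0.61 and 1.62 ± 0.59 without passing. Of 23 Hedgehog genes 3 were higher and 0 lower, in both counts (camera adjusted p = 0.403). These were the coreceptor genes Gas1 (1.31 ± 0.32) and Cdon (1.22 ± 0.26) and the transcription factor gene Gli3 (1.31 ± 0.32). Ptch1 differed by 0.55 ± 0.38, Gli1 by 1.05 ± 0.73, Gli2 by 0.77 ± 0.24, Smo by 0.69 ± 0.28 and Hhip by 0.16 ± 0.36, and the fold of Shh was at least 1.15, none past the threshold. Ptch1 was at -0.06 and Hhip at -0.15 after quantile normalization. Of 20 joint genes 3 were higher and 0 lower, in both counts (camera adjusted p = 0.434). Has2, a hyaluronan synthase gene, was higher by 2.69 ± 0.33 (adjusted p = 0.00322), the protease gene Htra1 by 1.32 ± 0.35, and Barx1 at least 1.20-fold, while the fold of Creb5, at least 2.06, did not pass (adjusted p = 0.147). Of these signalling and joint genes, Tgfbr1, Fzd6, Axin2, Gas1, Cdon, Gli3 and Htra1 did not pass after quantile normalization.

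Of 25 cartilage genes 2 were higher and 0 lower, in both counts, with a median of -0.11 (camera adjusted p = 0.374), and of -0.59 after quantile normalization (adjusted p = 0.196). Sox9 was higher by 2.32 ± 0.33 (adjusted p = 0.00502) and Sox6 by 1.15 ± 0.23 (adjusted p = 0.0153), and both lost the call after quantile normalization, with Sox9 at 0.40 and Sox6 at 0.49. Col2a1 differed by -0.02 ± 0.81 (adjusted p = 0.99), Acan by 0.27 ± 0.67 (adjusted p = 0.825), Ucma by 2.02 ± 0.70 and Sox5 by 1.61 ± 0.58. Acan was at -0.35 and Ucma at -0.05 after quantile normalization. Probe sets were chosen anew after that normalization, so the moves of Sox9 and Ucma may hold a change of probe set, which was not checked. Of 25 bone genes 1 was higher and 1 lower, in both counts, with a median of -0.15 (camera adjusted p = 0.0898). After quantile normalization the median was -0.58 (adjusted p = 0.0816), and without genes at background the list was then called down (adjusted p = 0.0252). As deposited it had an adjusted p = 0.714 with an estimated correlation. The lower gene was Mepe. Dmp1 differed by -2.69 ± 1.13 (adjusted p = 0.145), Omd by -2.44 ± 0.92, Phex by -2.01 ± 1.52, Ibsp by -1.31 ± 0.95, Col1a1 by -0.55 ± 0.58 and Sp7 by 0.67 ± 0.56. Sp7 was at -0.03 after quantile normalization.

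The other lists called in this comparison were called down with medians between -0.08 and -0.02, below a median of all genes of 0.21. These were endothelium and gut, lung, kidney and pancreas (camera adjusted p = 0.00317 each; adjusted p = 0.577 and 0.291 with an estimated correlation), Hox (0.00991; 0.577), skeletal muscle (0.0335; 0.714), heart muscle (0.0402; 0.521) and macrophage and leukocyte (0.0419; 0.676). After quantile normalization endothelium alone of these was called (median -0.28; adjusted p = 0.00646), while without genes at background it was not (adjusted p = 0.0554) but skeletal muscle was (median -0.57, adjusted p = 0.0252). Their members past the threshold were 1 higher and 2 lower for endothelium (1 and 1 adjusted over the list alone), 1 and 1 for gut, lung, kidney and pancreas (0 and 1), 2 and 2 for Hox (2 and 2), 1 and 0 for skeletal muscle (1 and 0), 0 and 1 for heart muscle (0 and 1) and 0 for macrophage and leukocyte.

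The remaining lists were not called. Higher and lower members were 4 and 0 for fibrous tissue, 4 and 0 for matrix remodelling (0 and 0 adjusted over the list alone), 4 and 0 for FGF (6 and 0), 4 and 0 for stress (6 and 1), 3 and 0 for liver, 2 and 1 for osteoclast, and 1 and 0 each for hypertrophic chondrocyte (0 and 0), neuron (0 and 0), epithelium and fat. No Notch, erythroid, glial or sex chromosome gene passed. Genes at background in both groups made up 290 of the 3440 called genes, 94 of the higher and 196 of the lower ones.

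The 3 prime minus 5 prime value of Gapdh was 5.94 ± 0.81 (SD, n = 3) in condyle and 4.66 ± 0.85 in fossa (exact permutation p = 0.1, the smallest possible), and that of Actb 6.64 ± 0.11 and 5.85 ± 0.94 (exact permutation p = 0.2). In whole body they were 5.85 ± 0.61 and 6.07 ± 0.44. The 3 prime minus middle value of Actb was 0.45 (log2) higher in fossa than in whole body (exact permutation p = 0.1) and differed by -0.23 in condyle (p = 0.2). Its condyle minus fossa difference was -0.68 (exact permutation p = 0.1), opposite in direction to the 3 prime minus 5 prime differences. In the comparison of condyle with fossa 49.7% of genes had 3 arrays beyond the other 3, where chance gives 10%, and the count of 3440 was between 2086 and 2241 without any single condyle array or without fossa array 3.

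Marker lists of other cell types varied between arrays of the same joint tissue. The mean log2 intensity of 25 epithelial genes was 7.04, 8.38 and 7.52 on condyle arrays 1, 2 and 3, and 8.03, 4.49 and 7.37 on fossa arrays 1, 2 and 3, against 6.48, 6.44 and 6.21 in whole body. That of 28 neuronal genes was 6.62, 5 and 7.78 in condyle and 5.03, 6.69 and 6.18 in fossa, against 6.09, 6.08 and 6.31 in whole body. That of 25 bone genes was 7.79, 6.66 and 6.65 in condyle and 6.56, 7.88 and 7.27 in fossa.

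**Figure D3:**
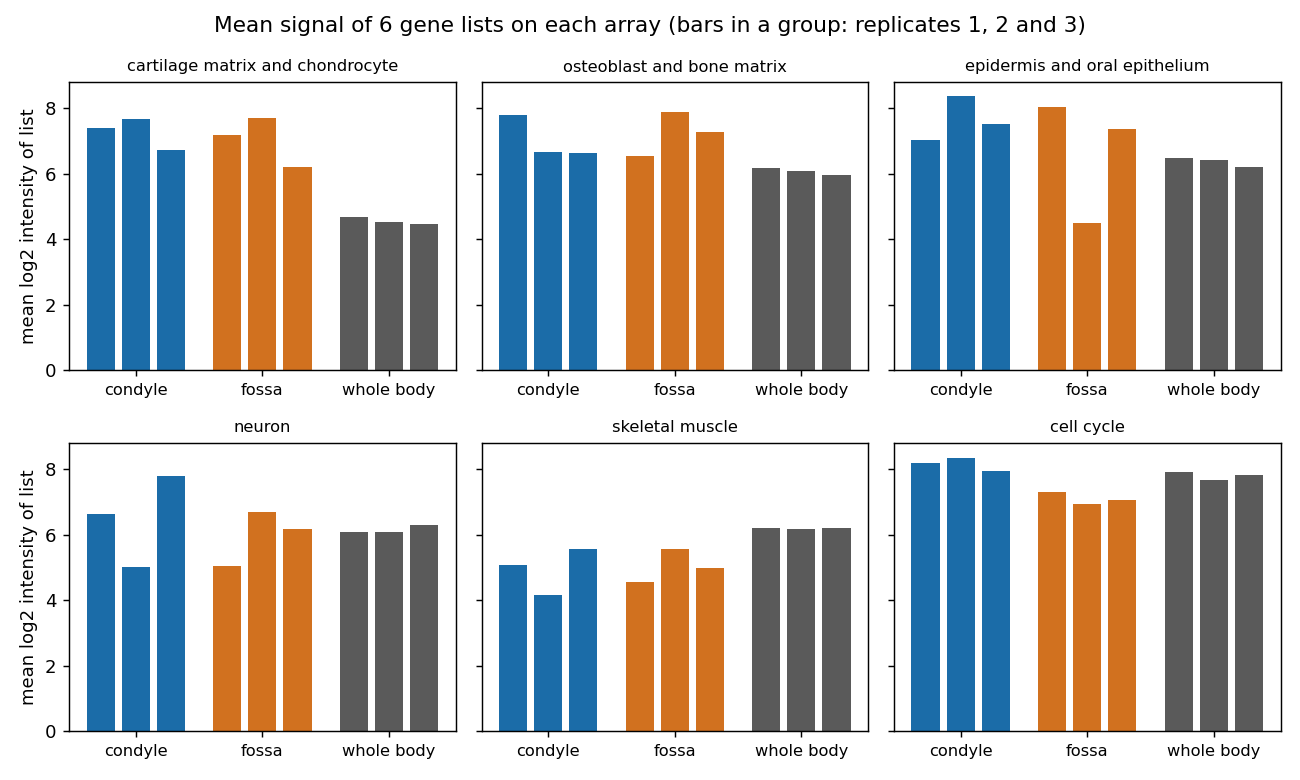
Mean log2 intensity of 6 gene lists on each of the 9 arrays, with bars for replicates 1, 2 and 3 of condyle, fossa and whole body. Epithelial genes were at 4.49 on fossa array 2 against 8.03 and 7.37 on the other fossa arrays, and cell cycle genes lay between 6.95 and 7.29 on the fossa arrays and between 7.94 and 8.34 on the condyle arrays.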

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

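A set of 69 genes was flagged because condyle and fossa differed from the whole body in opposite directions, with the difference between condyle and fossa called too. All 69 were higher in condyle and lower in fossa. The mean 75th percentile of the arrays ran in the same order, 4.85 in condyle, 4.45 in whole body and 4.18 in fossa (log2). The set was counted on the deposited scale only, so whether scaling sets this direction was not tested. Among them the condyle minus fossa difference was 3.67 for Tac1, the substance P gene, 3.29 for Lhx8, a transcription factor gene of the first pharyngeal arch, 3.13 for Txlna and 3.04 for Erlin2 (log2), which was at background on all 3 fossa arrays (at least 6.39-fold). Against whole body Tac1 differed by 1.70 in condyle and -1.98 in fossa, and Lhx8 by 1.74 and -1.55. The cell cycle list was flagged for the same reason, with a median condyle minus fossa difference of 1.12. After quantile normalization camera called this list in neither joint tissue against whole body. Probe sets without a single named gene were flagged because they were called higher than in whole body and lay above background on all 3 arrays but carry no gene here: 56 in condyle and 73 in fossa. With 3 arrays per group no array was tested as an outlier.

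Of the patterns weighed, the first was that many more genes were higher than lower in condyle against fossa; its tests were chosen only after the result was seen. The fossa arrays were dimmer over the upper part of their distribution, with a mean 75th percentile of 4.18 (log2) against 4.85 in condyle. Whether this set the share of higher genes was not decided. That share was 58.1% after quantile normalization, but this scaling brings the median difference close to 0 whatever the source. Of the higher genes 3.08% were at background in both groups. A gene raised in condyle tends to pass the limit there, so this low share cannot decide whether offsets near background play a part. With a common floor at the highest background limit 1757 of the 3053 higher genes and 38 of the 387 lower ones were still called. For the lower genes offsets near background could play a part, because 50.6% were at background in both groups (95% interval 45.5 to 55.7) against 27.5% of all tested genes. The interval is binomial and treats genes as independent, though all come from the same arrays. It does not measure the spread between samples. Of 27 control probe sets for Bacillus subtilis transcripts 7 were called lower and 0 higher in condyle. Whether tissue difference or array brightness set the direction stays open, but the cell cycle list was still called, with a median of 0.49 and an adjusted p = 2.08e-05, after quantile normalization without genes at background, though as deposited it had an adjusted p = 0.291 with an estimated correlation.

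The next pattern was the lower 18S ribosomal RNA signal on the condyle and fossa arrays; its tests were chosen only after the result was seen, and the first was replaced after its value was known. That test pooled condyle and fossa and put the 3 prime minus 5 prime value (log2, mean of Gapdh and Actb) at -0.19 ± 0.38 (SE) against whole body, which had argued against shorter RNA with a bound of 1. Taken apart, condyle lay at 0.33 ± 0.29 (95% interval -0.54 to 1.21) and fossa at -0.70 ± 0.54 (-2.74 to 1.33), so shorter RNA stays open in both. The fossa value leaned on fossa array 1, which had the highest background limit (3.52, log2). Its Gapdh value was 3.69 against 4.97 and 5.31 on fossa arrays 2 and 3. For Actb it was 4.79 against 6.15 and 6.60. In 18S signal the lowest whole body array lay 4.52 (log2) above the highest condyle or fossa array. This gap is the pattern itself and cannot speak for any source. A different RNA input or labelling could be the source. The labels give the same capture entry and RNA kit for all groups, and tissue and any difference in input go together here, so this stays open.

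The last pattern was that epithelial and neuronal genes differed between samples of the same tissue; its tests were chosen only after the result was seen. Of 25 epithelial genes, 100% were lowest on fossa array 2 among the fossa arrays, and of 28 neuronal genes 89.3% were highest on condyle array 3 among the condyle arrays. Overall brightness was argued against: the median deviations of -2.55 and 1.37 lay at percentiles 0 and 100 of 10000 lists matched on mean level. The central 95% of these lists ran from -0.07 to 0.22 and from -0.13 to 0.12. Different amounts of neighbouring epithelium and nerve in the samples may be the source, a hypothesis that these arrays leave open.

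The grouping itself was checked by splitting the arrays in other ways, a test chosen beforehand. In each of the 3 comparisons 1 of 10 splits, the real one, gave as many genes, and the highest other split gave 0, 0 and 1 genes for condyle and whole body, fossa and whole body, and condyle and fossa. These splits are too few for a share under 0.05. For the 3 groups together 1 of 100 drawn splits of 280 gave as many genes, the real one with 5119. The highest other split gave 700. The real split was always among those drawn, so 1 of 100 was the smallest share possible. This argues against a chance split for the 3 groups together. It does not decide condyle against fossa alone, nor handling that goes with tissue.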

How the results depend on the processing

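The largest rises and falls of condyle and of fossa against whole body kept their calls in every setting run for single genes (336 times each). Those of condyle against fossa kept them 297 times and lost them 36 times, in 6 of 16 genes. Over all settings, results for named genes, also those never called, stayed on their side of the threshold 3331 times, lost the call 255 times and gained it 85 times. Results for gene lists stayed 1537 times, lost the call 147 times, gained it 55 times and reversed 1 time. Signal over background limits what dim genes can show. The alternatives without genes at background and with a common floor were chosen after seeing the data. The cause of the moves was not tested.

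Quantile normalization gave 3152 genes over 3 groups (5119 in the main result) and 1178 genes (3440) and 3 lists (8) for condyle against fossa. Without genes at background it gave 2809 genes over 3 groups, and 379 genes and 4 lists for condyle against fossa. The common floor gave 3024 genes over 3 groups, 1893 for fossa against whole body (3559) and 1823 for condyle against fossa. Every probe set tested alone gave 8092, 6146 and 5998 probe sets in these results. Array weights gave 5022 genes for condyle against whole body (2398), 6514 for fossa against whole body and 5632 for condyle against fossa. A minimum fold of 2 left 1945 genes for fossa against whole body and 1743 for condyle against fossa.

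With an estimated correlation 1 list was called for condyle against whole body (16), 1 for fossa against whole body (13) and 0 for condyle against fossa. The fry test called 15 lists (8 up, 7 down), 10 (1 up, 9 down) and 9 (9 up, 0 down) in these comparisons, where camera called 2 up and 6 down for condyle against fossa. Centring on the median gave 5 lists for condyle against fossa and leaving out the dimmest 40% of genes gave 16. The skeletal muscle list of condyle against fossa, called down by camera with a median of -0.0476, had the direction up under fry (adjusted p = 0.966).

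Leaving out 1 array at a time gave 1470 to 2591 genes for condyle against whole body, 2343 to 3352 for fossa against whole body and 2086 to 3515 for condyle against fossa. For the latter it gave 4 to 10 lists, with 4 without condyle array 2 or fossa array 2. The genes shared by condyle and fossa against whole body numbered 722 to 1071 (1072).

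With the replicate number as a replicate block, 3724 genes differed over 3 groups, and 1691, 2779 and 2537 in the 3 comparisons, with 13, 13 and 8 lists. As a hint from the data only, condyle and fossa arrays of the same number correlated at -0.33, -0.44 and 0.15 across genes after removal of the group means, so not every array correlated best with its own number.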

Other observations

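The genes Fgfr3, Fgfr2 and Fgfr1 encode receptors for growth factors; the FGF list they belong to was not called in either joint tissue against whole body (camera adjusted p = 0.401 and 0.325). Fgfr3 was higher by 4.02 ± 0.34 (SE) in condyle and 3.45 ± 0.34 in fossa, Fgfr2 by 3.76 ± 0.63 and 2.91 ± 0.63, and Fgfr1 by 3.18 ± 0.31 and 2.16 ± 0.31. Their adjusted p were 0.000894 and 0.001 for Fgfr3, 0.0108 and 0.019 for Fgfr2, and 0.00169 and 0.00431 for Fgfr1. Dusp6, a feedback inhibitor gene of this pathway, was lower in fossa than in whole body by -2.62 ± 0.30 and higher in condyle than in fossa by 2.16 ± 0.30 (adjusted p = 0.00467). Myc, a growth regulator gene, was higher in condyle than in fossa by 2.27 ± 0.41 (adjusted p = 0.0123).

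Has2, a hyaluronan synthase gene, was lower in fossa than in whole body by -1.77 ± 0.33 (adjusted p = 0.011). The type VI collagen genes Col6a1 and Col6a2 were higher than in whole body by 3.41 ± 0.38 and 2.87 ± 0.27 in condyle and by 2.32 ± 0.38 and 2.30 ± 0.27 in fossa. Kera and Tnmd, genes of fibrous tissue and tendon, were lower in fossa than in whole body by -2.94 ± 0.68 and -2.44 ± 0.48.

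Ttr, the transthyretin gene, was at 9.81, 11.77 and 15.23 (log2) on condyle arrays 1, 2 and 3, and at 5.58, 4.24 and 15.06 on fossa arrays 1, 2 and 3. On the whole body arrays it was at 14.88, 14.69 and 14.77. Clic6 was at 2.64, 3.50 and 5.77 on the fossa arrays. Dmp1 was at 9.69, 5.70 and 6.44 on the condyle arrays and at 8.25, 10.94 and 10.70 on the fossa arrays.

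Xist, the RNA of the inactive X chromosome, was at 11.37, 11.56 and 11.49 in condyle, 8.80, 11.33 and 11.35 in fossa and 10.18, 4.04 and 6.52 in whole body. Eif2s3y, a Y chromosome gene, was at 8.84 on whole body array 3 and between 2.64 and 3.54 on the other arrays. The Y chromosome genes Uty and Kdm5d were at 3.13 and 2.5 on whole body array 3, under its background limit of 3.36. The signal of the B1 repeat probe was 9.47 ± 0.99 (SD, n = 3) in condyle, 9.24 ± 0.45 in fossa and 12.72 ± 0.21 in whole body.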
